A study of Mus musculus with 6 samples.

How the data were processed

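Bone marrow RNA of 6 mouse samples, 3 control and 3 CUMS (stressed for 4 weeks), was sequenced by the authors on an Illumina instrument with paired reads of 151 bp after TRIzol extraction and a TruSeq library kit. The submitters' processing notes name bcl2fastq 2.19, cutadapt 1.16.5, HISAT2 2.1, featureCounts 1.6.4 and DESeq2 2.11.40.6 with the mm10 build; which of these made the deposited values, and whether strand was used, is not stated. The deposited values are FPKM. No label or header names the unit, which was read from the values: they are not whole, each library sums to 561563 to 658595, and value times exon length in kilobases sums to 937809 to 987723 per library, as FPKM does. The authors recorded no scaling between samples. Each file held 47561 entries, 46333 of them genes by RefSeq symbol.

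Depth in counts is not given. The spacing of the lowest values put it at roughly 17500000 to 20600000 fragments per library, but values did not fall on whole multiples, so counts were not recovered and no counting intervals are given. Precision rests on the spread between the 3 libraries of a group. The labels do not say whether the libraries came from separate animals, so the p-values measure only the spread between these samples, and with 3 against 3 libraries an exact permutation test of 1 gene cannot go below 0.1.

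The tests were fixed before the data were examined, and they assumed counts; for a normalized unit the rule fixed at the same time was limma-trend on log2(value + 1), which was used (R 4.3.3, limma 3.58.1; Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 for tables and plots). Genes with at least 1 FPKM in at least 3 of the 6 libraries were tested (12302), with group as the only term, a pseudocount of 1, and a Benjamini-Hochberg adjusted p under 0.05 as the threshold. Log2 changes are CUMS minus control on log2(FPKM + 1), so that they are smaller than the ratio of the means for genes near the floor. The file headers hold a code, 1 for replicate 1 of each group and 2 for the other 4 libraries, whose meaning is not stated. It was read as a sequencing run, and run 1 and run 2 stand for it throughout. The fit was tested on simulated data with an effect of this code like that of the files: it recovered 69% of 100 genes changed 2-fold and 10% of 100 genes changed 1.5-fold with 2 false calls among 82, and with the run as a term 93% and 78% with 12 false calls among 197.

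The replicate block was checked because titles carry a replicate number. The deviations of libraries from their group means correlated across genes by 0.689, 0.452 and 0.363 for replicates with the same number, and by 0.459 and 0.362 for replicates 2 and 3 crossed. Replicates 2 and 3 thus correlated about as much crossed as with the same number, so no pairing beyond the header code was seen among them. Replicate 1 of both groups shared the code read as run 1, so its correlation cannot be told apart from that code. No source names the replicates as pairs. Values with the block are given beside those without it for calls of named genes and lists that changed, and for the counts of list members.

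Gene lists (35, with 561 entries, all found in the files) were fixed with the tests; their members cover neutrophil granules, mature neutrophils, monocytes, other marrow cell types, stress hormone and interferon responses, the cell cycle, the mitochondrial genome, histones and checks of sex, handling and hour of collection. Lists with at least 5 tested members were compared with the other genes by camera from limma with a preset correlation of 0.01, adjusted over 32 lists. The calls that held with a correlation estimated per list were those of the interferon, immediate-early, glucocorticoid, histone and inflammatory lists. None held when the estimated correlation was joined to the replicate block or to the run code as a term. Joined to the run term, the camera adjusted p was 0.113 for the interferon, glucocorticoid and histone lists. It was 0.122 for the immediate-early and inflammatory lists. In the simulated data the combination with the block also missed a list shifted by 0.5 (camera adjusted p = 0.365 with the effect of the code, 0.224 without). That with the run term missed it with the effect of the code (0.0831) and found it without (0.0377). Each simulation was 1 draw with independent genes, so it covers no list whose members vary together. Within that limit, a call lost with the block says little against a list. Fry from limma was run as an alternative. The count adjusted over the list alone uses the members of 1 list as the family.

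Named genes followed a rule fixed with the tests: the 10 largest increases and 10 largest decreases among called genes with a mean log2 value of at least 1 and groups that did not overlap, up to 4 members with the smallest p in each list described, and a fixed set always, among them Avpr1a, Avpr1b, Avpr2, Csf3r, Csf1r, Nr3c1, Fkbp5, Mpo, Elane, Ly6c2, S100a8 and Hbb-bs. Others were chosen after their values were seen and are named so. Coordinates are those of the RefSeq annotation of GRCm38.p6, the assembly of mm10, and overlaps and exon lengths those of GENCODE M21.

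Alternatives were scaling by median ratios or to the same total, haemoglobin, immunoglobulin and mitochondrial genes left out, no filter or a stricter one (mean of at least 2 FPKM), the replicate block, each library left out in turn, at least a 2-fold change, and an adjusted p under 0.1. A pseudocount of 0.1, no intensity trend, sample quality weights, the run code as a term, the 4 libraries of run 2 alone and quantile normalization were chosen after seeing the data. All 6 libraries were used, and no column of values was left out.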

Results

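RNA from mouse bone marrow was sequenced in 6 libraries, 3 from control mice and 3 from mice kept under chronic unpredictable mild stress (CUMS), a rodent procedure of changing mild stressors, for 4 weeks. Paired reads of 151 bp gave FPKM values (fragments scaled by transcript length and library depth) for each gene. The files held no counts, so the depth was known only roughly, from the spacing of the lowest values, as 17500000 fragments in CUMS replicate 2 and 20200000 to 20600000 in the other libraries. Between 21334 and 23224 genes had a value above 0 per library. Erythrocyte and neutrophil transcripts made up much of each library: the haemoglobin genes took 28.8% to 29.2% of the summed FPKM in controls and 31.7% to 35.2% in CUMS, and S100a8 with S100a9, which encode the main calcium-binding proteins of neutrophils, 5.83% to 7.14% and 5.50% to 6.17%. Transcripts of the mitochondrial genome took 3.57% to 4.46% of the summed FPKM in controls and 2.35% to 3.12% in CUMS.

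The comparison of CUMS with control asked which transcripts of the marrow differed after the stress, and, as the series title names myelopoiesis, whether genes of the neutrophil and monocyte lineages were among them. In CUMS marrow interferon-stimulated genes were lower as a list, and immediate-early, glucocorticoid-responsive and inflammatory genes were higher. These calls held with an estimated correlation but not when it was joined to the replicate block or to the run code as a term. The combination with the block also missed a shifted list in the simulated data. That with the run term missed it only with the effect of the code. Monocyte genes were lower, and genes of basophils, mast cells and eosinophils higher, by camera with its preset correlation (adjusted p = 0.0633 and 0.227 with an estimated correlation). Neutrophil granule and mature neutrophil genes did not pass the test as groups in the main fit. The azurophil granule list lay near the threshold, towards higher (camera adjusted p = 0.0606). Its adjusted p was 0.0245 with the replicate block, 0.671 with an estimated correlation and 0.319 with both. With limma on log2(FPKM + 1), 132 of 12302 tested genes differed at an adjusted p under 0.05, 76 higher and 56 lower in CUMS. The 3 CUMS libraries lay on 1 side of the 3 control libraries for all 132, and for 2718 of all tested genes (22.1%). Chance gives 10% per gene if the libraries are exchangeable, which a code in the file headers that moved many genes puts in doubt. The share was not tested against chance. The share of higher genes among those called was 57.6%, but 39.2% after scaling the libraries to the same total, which moved the median log2 change of all genes from −0.0017 to −0.0359.

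**Figure D1:**
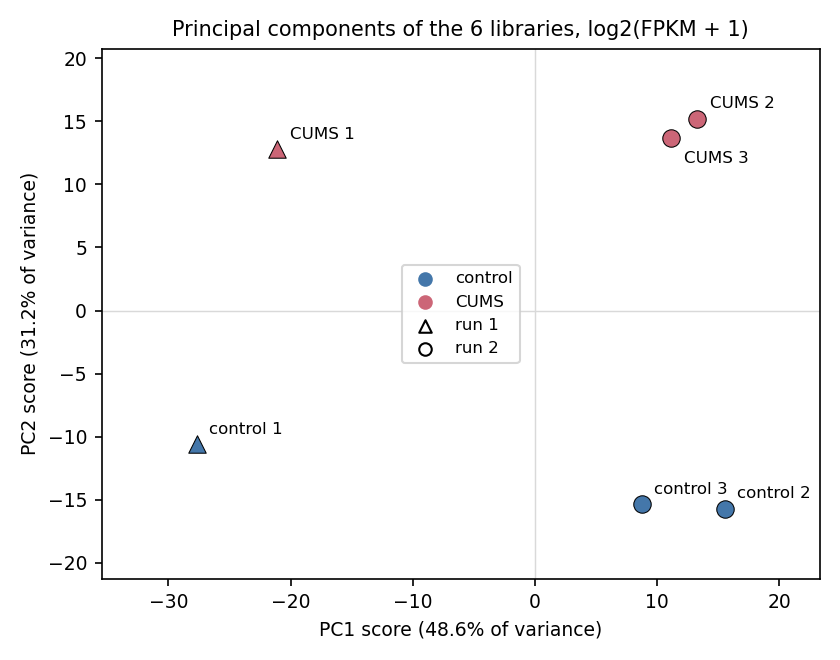
Scores of the 6 libraries on the first and second principal components of log2(FPKM + 1), coloured by group, with triangles for run 1 and circles for run 2, a code in the file headers that was read as a sequencing run though its meaning is not stated. The horizontal axis (48.6% of the variance) parts the values of this code, and the vertical axis (31.2%) parts CUMS from control.

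The largest component of the spread between the libraries followed a code in the file headers, which was read as a sequencing run (run 1 and run 2) although its meaning is not stated. Replicate 1 of each group carried run 1 and the other 4 libraries run 2, as the plot of the principal components shows, and 3747 genes differed between the runs at an adjusted p under 0.05. With the replicate block, 959 genes differed between CUMS and control (429 higher, 530 lower), with the run as a term 1645 (746 higher, 899 lower), and in the 4 libraries of run 2 alone 2173 (1085 higher, 1088 lower). All 132 genes were called again in each of these 3 fits. Leaving out 1 library gave 262 genes without control replicate 1, 33 without control replicate 2, 17 without control replicate 3, 72 without CUMS replicate 1, 19 without CUMS replicate 2 and 17 without CUMS replicate 3. Of the 132 genes, 129, 31, 16, 60, 19 and 17 were kept in these fits. Each of these fits divided the code unevenly between the groups, so an effect of the code did not cancel in them. All 132 kept their direction, which leaving out a library could not turn, since their groups did not overlap.

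Among genes with a mean log2 value of at least 1, the 10 largest increases that passed the test were those of Igkv3-10, Ddx3y, Rgs1, LOC115489609, Eif2s3y, Egr1, Ighg3, Igkv3-4, Cd69 and Ccl4. Igkv3-10, an immunoglobulin kappa variable segment (chromosome 6, 70572633 to 70573230, GRCm38), rose from 6.06 ± 0.680 to 26.4 ± 2.73 FPKM (mean ± SD, n = 3 libraries each; log2 change 1.96, SE 0.119, limma adjusted p = 0.00116). Rgs1, a regulator of G protein signalling in lymphocytes, rose from 2.30 ± 0.353 to 8.75 ± 0.394 FPKM, and Cd69, an early activation marker of lymphocytes, from 6.45 ± 0.774 to 17.7 ± 1.00 FPKM (log2 changes 1.57 and 1.33, adjusted p = 0.00282 and 0.00419). LOC115489609, a small nucleolar RNA, rose by 1.48 on the log2 scale, Ighg3, an immunoglobulin heavy-chain constant gene, by 1.37, and Igkv3-4 by 1.34 (adjusted p = 0.020, 0.0179 and 0.0135). LOC115489609 (chromosome 2, 130276237 to 130276369) is shorter than the 151 bp reads. Its FPKM may hold reads of a longer transcript, which was not tested. The Y-linked genes Ddx3y and Eif2s3y rose from 3.31 ± 0.50 to 12.0 ± 1.53 FPKM and from 11.2 ± 1.55 to 31.8 ± 2.65 FPKM, and both had an adjusted p of 0.00419. In the list of sex-chromosome genes 2 of the 4 tested members rose, and all 4 were higher when adjusted over the list alone. The other members, Uty and Kdm5d, had log2 changes of 0.78 and 0.72 (adjusted p = 0.0712 and 0.0723, with the replicate block 0.0147 and 0.0118). Xist, the transcript of the inactive X chromosome in female cells, was at most 0.0312 FPKM in any library.

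With the same minimum, the 10 largest decreases that passed were those of Erdr1-2, Erdr1, Ifi27l2a, Oasl2, Ifit3, Oas1a, Fcgr1, Rtp4, Apoc2 and Usp18. Erdr1-2 fell from 49.7 ± 2.28 to 2.37 ± 0.477 FPKM and Erdr1 (chromosome X, 170010526 to 170018797) from 36.6 ± 11.2 to 2.54 ± 0.673 FPKM (log2 changes −3.92 and −3.38, SE 0.122 and 0.244, adjusted p = 2.2e-05 and 0.00282). Reads of these near-identical copies cannot be assigned to 1 of them with certainty. Fcgr1, a high-affinity IgG receptor of monocytes and macrophages, fell by 1.21 on the log2 scale (from 5.82 ± 0.706 to 1.94 ± 0.140 FPKM), and Apoc2, an apolipoprotein, by 1.14 (adjusted p = 0.00717 and 0.00877). The other 6 genes are interferon-inducible, and Ifi27l2a fell the most of them, from 114 ± 10.9 to 38.8 ± 7.10 FPKM (log2 change −1.54, adjusted p = 0.00601). Of 41 named genes whose change passed the test, 13 were called in all 6 fits that left out 1 library: Igkv3-10, Ddx3y, Rgs1, Eif2s3y, Cd69, Erdr1-2, Erdr1, Ifi27l2a, Oasl2, Oas1a, Usp18, Epx and Cxcl2.

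Interferon-stimulated genes were lower in CUMS. Of 19 tested members of the list 11 fell, 18 were lower when adjusted over the list alone, and the median log2 change was −0.70 (−0.86 in the pair of run 1, −0.63 in run 2). Oasl2, an antiviral oligoadenylate synthetase-like protein, fell from 15.8 ± 1.29 to 6.02 ± 0.679 FPKM (adjusted p = 0.00551), Oas1a from 18.6 ± 0.697 to 7.40 ± 0.705 FPKM (adjusted p = 0.00419), and Usp18, which restrains interferon receptor signalling, from 10.2 ± 0.608 to 4.13 ± 0.106 FPKM (adjusted p = 0.00419). Irf7, a transcription factor that amplifies the interferon response, fell from 41.1 ± 0.911 to 19.7 ± 2.71 FPKM (adjusted p = 0.00911). The list was lower than the other tested genes by camera from limma (adjusted p = 1.95e-23, and adjusted p = 0.0115 with an estimated correlation). With the replicate block 17 members fell, and the adjusted p with an estimated correlation was then 0.253 (0.113 with the run term instead of the block). The combination with the block also missed a shifted list in the simulated data. Without control replicate 2 or CUMS replicate 1 the number that fell was 5, and without control replicate 3, CUMS replicate 2 or CUMS replicate 3 it was 3.

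**Figure D2:**
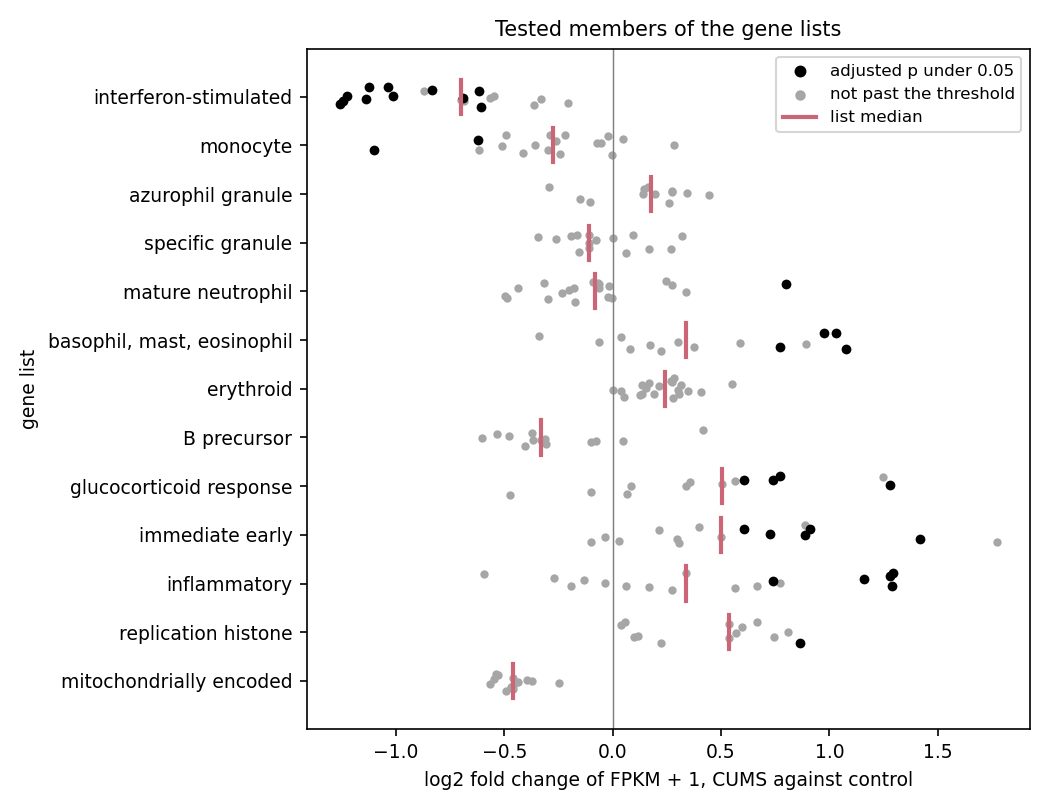
Log2 change of FPKM + 1 (CUMS against control, horizontal axis) of each tested member of 13 gene lists, with black points for genes at an adjusted p under 0.05 and red bars at the list medians. All 19 interferon-stimulated genes lie below 0 and all 20 erythroid genes above 0, where scaling to the same total left 18 of these above.

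Monocyte genes were lower in CUMS as a list by camera (adjusted p = 8.59e-06). The adjusted p was 0.0633 with an estimated correlation, and 0.253 with both that and the replicate block. Of 18 tested members 2 fell, 10 were lower when adjusted over the list alone, and the median log2 change was −0.28 (−0.30 in run 1, −0.26 in run 2). Cx3cr1, the fractalkine receptor, fell from 12.3 ± 1.347 to 5.17 ± 0.357 FPKM (log2 change −1.10, SE 0.111, adjusted p = 0.00817). Csf1r, the receptor of macrophage colony-stimulating factor (chromosome 18, 61105572 to 61131139), fell from 46.7 ± 2.78 to 30.1 ± 2.67 FPKM (log2 change −0.62, SE 0.10, adjusted p = 0.0338); its exons overlap those of Hmgxb3 on the opposite strand over 873 bp. Ms4a4c and Ccr2, the chemokine receptor of classical monocytes, had log2 changes of −0.62 and −0.51 (adjusted p = 0.0591 and 0.070, with the replicate block 0.0171 and 0.0196), and 9 members fell with the block. Ly6c2, a surface protein of classical monocytes, was at 708 ± 123 and 727 ± 49.3 FPKM (log2 change 0.05, adjusted p = 0.914). No member was called without control replicate 3, CUMS replicate 2 or CUMS replicate 3, 1 without control replicate 2 or CUMS replicate 1, and 3 without control replicate 1.

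Genes of the neutrophil lineage gave no call as groups. None of the 12 azurophil granule genes, which mark promyelocytes, passed the test (132 of all 12302 tested genes did, and 1898 had an unadjusted limma p under 0.05). The median log2 change of the 12 was 0.18 (0.15 in run 1, 0.17 in run 2). Mpo, myeloperoxidase, was at 524 ± 72.6 FPKM in controls and 640 ± 140 in CUMS (log2 change 0.27, SE 0.176, adjusted p = 0.517, with the run term 0.0453), Elane, neutrophil elastase, at 684 ± 128 and 757 ± 135 (0.15, SE 0.178, adjusted p = 0.764), and Ctsg, cathepsin G, at 148 ± 33.9 and 198 ± 8.4 (0.44, SE 0.155, adjusted p = 0.237, with the replicate block 0.0476). With the block 1 member rose, with the run term 4, and without control replicate 1, 3 did. The median was 0.27, 0.10 and 0.15 without control replicates 1, 2 and 3, and 0.04, 0.25 and 0.24 without CUMS replicates 1, 2 and 3. Camera gave the azurophil list an adjusted p of 0.0606 towards higher in CUMS. It passed with the replicate block (0.0245), without control replicate 1 (0.00217), CUMS replicate 2 (0.00897) or CUMS replicate 3 (0.0335), and did not without control replicate 2 (0.355), control replicate 3 (0.110) or CUMS replicate 1 (0.607). The adjusted p with an estimated correlation was 0.671, and 0.319 with that and the block. Of the 15 specific granule genes none passed either (median −0.11, camera adjusted p = 0.737 towards lower, but 0.316 without control replicate 1 and 0.955 without CUMS replicate 3 towards higher). Olfm4 had a log2 change of 0.32 and Cebpe one of −0.26 (adjusted p = 0.262 and 0.309). With the run term 2 specific granule genes rose and 1 fell.

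Among 20 mature neutrophil genes Trem1, a receptor that amplifies inflammatory responses, rose from 15.98 ± 0.609 to 28.7 ± 3.35 FPKM (log2 change 0.80, SE 0.108, adjusted p = 0.0196). Adjusted over the list alone, 1 member was higher and 3 were lower, and 16 of the 20 had values towards lower (median −0.08, −0.20 in run 1 and −0.07 in run 2; camera adjusted p = 0.239). The adjusted p was 0.0409 after scaling to the same total, while with quantile normalization 10 had values towards lower and 8 towards higher (median −0.03). With the replicate block 1 rose and 4 fell. Mmp9, gelatinase B, and G0s2 had log2 changes of −0.50 and −0.49 (adjusted p = 0.0776 and 0.0816, with the replicate block 0.0240 and 0.0246). S100a8 was at 21080 ± 4137 and 19950 ± 382 FPKM (log2 change −0.06, adjusted p = 0.928) and Csf3r, the receptor of granulocyte colony-stimulating factor, at 164 ± 26.5 and 143 ± 5.87 FPKM (log2 change −0.18, adjusted p = 0.589). Without control replicate 2, control replicate 3, CUMS replicate 2 or CUMS replicate 3 no member rose.

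Genes of basophils, mast cells and eosinophils were higher in CUMS as a list by camera (adjusted p = 2.86e-06), but adjusted p = 0.227 with an estimated correlation. In this list 4 of 14 tested members rose, 6 were higher when adjusted over the list alone, 6 rose with the replicate block, and the median log2 change was 0.34 (0.27 in run 1, 0.42 in run 2). The 4 encode eosinophil granule proteins and were singled out by the test, not fixed as a group: Epx, eosinophil peroxidase, rose from 37.8 ± 1.84 to 75.4 ± 3.48 FPKM (log2 change 0.98, SE 0.087, adjusted p = 0.00551), Prg2, major basic protein, from 500 ± 85.2 to 1013 ± 14.4 (1.03, SE 0.140, adjusted p = 0.0196), and the eosinophil ribonucleases Ear6 and Ear1 by 1.08 and 0.77 (adjusted p = 0.00877 and 0.0306). The Ear genes are close paralogs whose reads are hard to part. The number that rose was 6 without control replicate 1, 2 without control replicate 2 or CUMS replicate 1, and 1 without control replicate 3, CUMS replicate 2 or CUMS replicate 3.

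**Figure D3:**
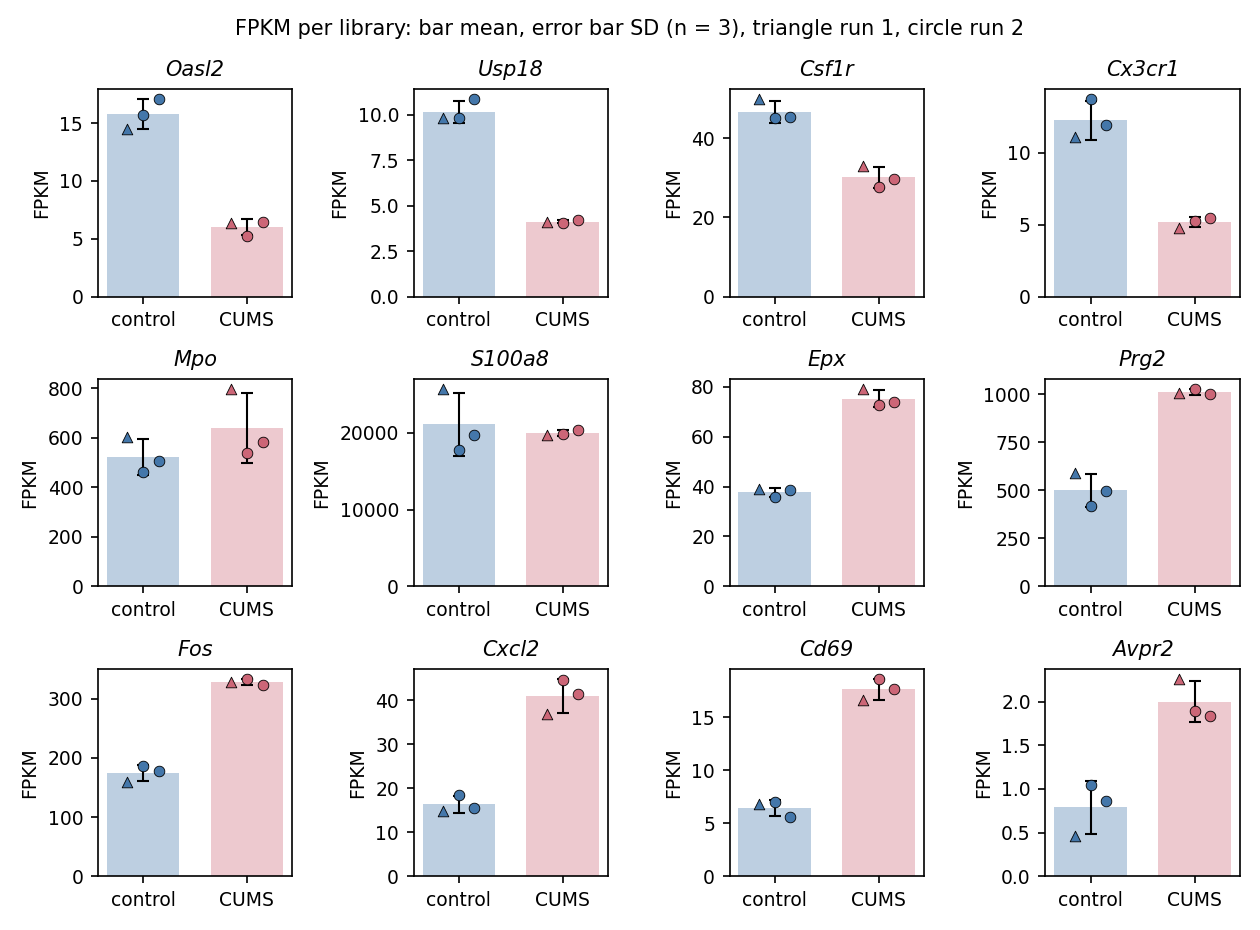
FPKM of 12 genes in each library, with bars for group means, error bars for the SD (n = 3), triangles for run 1 and circles for run 2. Control and CUMS libraries overlap for Mpo and S100a8 and lie apart for the other 10 genes.

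Inflammatory genes were higher in CUMS as a list, with 4 chemokines among the 5 that rose. The 8 tested genes of the Ccl family, a group chosen after the values were seen, were split. Of these 4 had values towards higher and 3 rose, and the median log2 change was −0.03 (−0.15 in run 1, 0.06 in run 2). Among the 5 tested secreted myeloid growth factors and chemokines, Cxcl2, a neutrophil attractant, rose from 16.3 ± 1.93 to 41.0 ± 3.93 FPKM (log2 change 1.28, adjusted p = 0.00565) and Ccl2, a monocyte attractant, from 0.571 ± 0.215 to 2.52 ± 0.630 FPKM (1.161, adjusted p = 0.0278), and 3 members were higher when adjusted over the list alone, as many as rose with the replicate block. Cxcl12, which retains progenitors and neutrophils in the marrow, had a log2 change of 0.34 (adjusted p = 0.151, with the replicate block 0.0320), and Flt3l one of −0.06 (adjusted p = 0.877). Of 17 inflammatory genes 5 rose, and 10 were higher and 2 lower when adjusted over the list alone (median 0.34; 0.36 in run 1, 0.35 in run 2). Besides Cxcl2 and Ccl2 these were Ccl3, from 10.6 ± 1.81 to 27.1 ± 1.52 FPKM (1.29, adjusted p = 0.00717), its paralog Ccl4 (1.29, adjusted p = 0.0115), and Socs3, an inhibitor of cytokine receptor signalling, from 10.4 ± 0.914 to 18.02 ± 1.49 FPKM (0.74, adjusted p = 0.0245). With the replicate block 9 inflammatory genes rose and 1 fell. By camera the adjusted p was 3.44e-06 for the inflammatory list (adjusted p = 0.0442 with an estimated correlation, 0.296 with that and the block) and 0.00117 for the myeloid cytokines (adjusted p = 0.0929 with an estimated correlation). Inflammatory genes that rose numbered 3 without control replicate 2 or CUMS replicate 1, 2 without CUMS replicate 2, and 1 without control replicate 3 or CUMS replicate 3. For the myeloid cytokines the number was 1 without any 1 library but control replicate 1.

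Immediate-early and glucocorticoid-responsive genes were higher in CUMS. Of 15 tested immediate-early and heat shock genes 5 rose, and 11 were higher when adjusted over the list alone (median 0.50; 0.59 in run 1, 0.39 in run 2). Fos rose from 175 ± 13.7 to 329 ± 5.24 FPKM (log2 change 0.91, adjusted p = 0.00887), Jun from 16.4 ± 0.774 to 31.3 ± 1.83 (0.89, adjusted p = 0.00839) and Egr1 from 16.4 ± 4.20 to 45.2 ± 9.17 (1.42, adjusted p = 0.0285). Of 13 genes induced by glucocorticoids in many tissues 4 rose, and 9 were higher when adjusted over the list alone (median 0.51; 0.39 in run 1, 0.52 in run 2). Mt2, a metallothionein, rose from 17.1 ± 3.38 to 42.6 ± 4.00 FPKM and Ddit4 from 11.9 ± 0.863 to 21.1 ± 0.566 (adjusted p = 0.0120 each). The other 2 were Klf9 (from 1.70 ± 0.122 to 3.51 ± 0.349, adjusted p = 0.0293) and Dusp1, a phosphatase that is also in the immediate-early list (from 141 ± 3.17 to 216 ± 18.3, adjusted p = 0.0331). Fkbp5, a co-chaperone of the glucocorticoid receptor, had a log2 change of 0.36 (12.6 ± 0.565 and 16.4 ± 0.661 FPKM, adjusted p = 0.118, with the replicate block 0.0351), and Nr3c1, the glucocorticoid receptor, one of 0.03 (adjusted p = 0.951). With the replicate block 10 immediate-early genes rose, and 9 glucocorticoid-responsive genes rose and 1 fell. Camera gave adjusted p = 2.10e-09 and 1.17e-07 for the immediate-early and the glucocorticoid list, and adjusted p = 0.0377 and 0.0414 with an estimated correlation (0.284 and 0.253 with that and the block). No member of either list rose without control replicate 3, CUMS replicate 2 or CUMS replicate 3; without control replicate 2 the numbers were 2 and 1, and without CUMS replicate 1 the glucocorticoid list had 2.

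The vasopressin receptors Avpr1a and Avpr1b were at or near the limit of the files. Avpr1a was listed at 0 in all 6 libraries and Avpr1b at 0 in all but CUMS replicate 2 (0.0105 FPKM), so a difference could not be assessed. The cause of the zeros was not tested. Avpr2 (chromosome X, 73891765 to 73894428), the receptor that mediates the antidiuretic action of vasopressin in the kidney, was at 0.789 ± 0.304 FPKM in controls and 2.00 ± 0.233 in CUMS (log2 change 0.76, SE 0.158, adjusted p = 0.0759, with the replicate block 0.0317). Its exons overlap those of Arhgap4, at 69.3 ± 8.06 and 57.0 ± 3.94 FPKM, over 2347 bp on the opposite strand, and the labels do not say whether strand was used in counting. The list of the vasopressin system and receptors of stress hormones and transmitters, with 5 tested genes, gave no call (1 higher when adjusted over the list alone, camera adjusted p = 0.405).

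Erythroid, cell-cycle and histone genes had values towards higher in CUMS, and B-precursor genes and the mitochondrial genome towards lower. All 20 erythroid genes had values towards higher (median log2 change 0.24), though 18 did and 1 had one towards lower after scaling to the same total (median 0.20). With quantile normalization, which gives genes of the same rank in every library the same value, 16 did and 0 had one towards lower (median 0.17). None of the 20 passed the main test, 2 did when adjusted over the list alone, 4 rose with the replicate block and 1 without control replicate 1. Rhag and Car1 had log2 changes of 0.35 and 0.55 (adjusted p = 0.109 and 0.121, with the replicate block 0.0273 and 0.00742), and Hbb-bs, an adult beta-globin gene, one of 0.31 (adjusted p = 0.624). No gene of 24 in the cell-cycle list passed, 21 had values towards higher (median 0.19; 19 of them after scaling to the same total), and 5, among them Rrm2 and Ccne1, rose with the replicate block (adjusted p = 0.0362 and 0.0221). Of 13 replication-dependent histone genes, whose transcripts lack a poly(A) tail, H1f5 rose from 4.00 ± 0.238 to 8.11 ± 0.556 FPKM (log2 change 0.87, adjusted p = 0.0120), and 8 were higher when adjusted over the list alone (6 with the replicate block, adjusted over all genes). Camera gave adjusted p = 1.07e-04 for the erythroid, 5.73e-05 for the cell-cycle and 3.86e-07 for the histone list, and adjusted p = 0.143, 0.355 and 0.0442 with an estimated correlation (0.253 for the histone list with that and the block). H1f5 was not called without control replicate 2, control replicate 3, CUMS replicate 2 or CUMS replicate 3, and 2 histone genes rose without control replicate 1.

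All 13 protein-coding genes of the mitochondrial genome were lower, with a median log2 change of −0.46 (−0.58 in run 1, −0.42 in run 2). None passed the test over all genes, 9 were lower when adjusted over the list alone, and 10 fell with the replicate block. CYTB was at 2267 ± 88.4 and 1553 ± 104 FPKM (log2 change −0.55, adjusted p = 0.0824, with the replicate block 0.0168). The 22 nuclear genes of oxidative phosphorylation had a median of 0.05 (−0.17 in run 1, 0.09 in run 2; camera adjusted p = 0.637), which was 0.14 without control replicate 1 and −0.06 without control replicate 2. Of 13 pro-B and pre-B cell genes none passed, and 6 were lower and 1 higher when adjusted over the list alone (median −0.33; 5 fell and 1 rose with the replicate block). Rag2, a recombinase gene, and Dntt had log2 changes of −0.54 and −0.48 (adjusted p = 0.0725 and 0.151, with the replicate block 0.0246 and 0.0226), and Il7r one of 0.42 (adjusted p = 0.154, with the replicate block 0.0247). Camera gave adjusted p = 1.17e-07 for the mitochondrial and 0.00117 for the B-precursor list, and adjusted p = 0.286 and 0.0929 with an estimated correlation.

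The calls of several other lists changed when single libraries were left out, which also divided the run code unevenly between the groups. Resident macrophage genes were lower by camera (adjusted p = 0.0394), but adjusted p = 0.355 with an estimated correlation, 0.0618 with the replicate block, 0.196 without control replicate 1, 0.0504 without CUMS replicate 1 and 0.0707 without CUMS replicate 2. Stromal and bone genes were higher (adjusted p = 0.0262, but adjusted p = 0.173 with an estimated correlation, 0.174 with no filter, 0.0531 without control replicate 2 and 0.0504 without CUMS replicate 1), with Col1a2 alone passing (log2 change 0.62, adjusted p = 0.0293). Myeloid transcription factors and growth factor receptors, with Csf1r lower and Socs3 higher, passed with the replicate block (adjusted p = 0.0308), without control replicate 1 (0.0129) or without CUMS replicate 1 (0.0342), against 0.0692 in all 6 libraries. With an estimated correlation the adjusted p was 0.355, and 0.668 with that and the block. T and NK cell genes had an adjusted p of 0.0591 (0.0389 without control replicate 1, 0.0114 without CUMS replicate 2) and circadian clock genes one of 0.0692 (0.0415 without control replicate 2, 0.0431 without control replicate 3), and for both adjusted p = 0.355 with an estimated correlation. Per1, a clock gene that glucocorticoids also induce, was at 5.42 ± 2.16 FPKM in controls and 13.9 ± 3.62 in CUMS (log2 change 1.25, SE 0.292, adjusted p = 0.0997, with the replicate block 0.00210). Dendritic cell genes had an adjusted p of 0.104 (0.0402 after scaling to the same total, 0.0688 with the replicate block, 0.0482 with the run term), and adjusted p = 0.293 with an estimated correlation. Ribosomal protein genes had one of 0.239 (1.79e-05 without control replicate 1), and so did unfolded protein response genes (0.00347 without control replicate 1). Dnajb9 rose among the latter (log2 change 0.62, adjusted p = 0.0385), and Chac1 had a log2 change of −0.61 (adjusted p = 0.0630, with the replicate block 0.0221). For oxidative phosphorylation the adjusted p without control replicate 1 was 0.0102. Stem and progenitor, B cell and plasma cell genes each had an adjusted p of 0.346, megakaryocyte genes 0.809, glycolysis genes and osteoclast genes 0.829, and endothelial genes 0.987. For the megakaryocyte and glycolysis lists the median was negative (−0.01 and −0.03) while camera's direction was higher. With the replicate block 1 resident macrophage gene rose and 5 fell, 3 stromal and bone genes rose, 1 myeloid regulator rose and 3 fell, 1 B cell gene rose and 4 fell, 2 dendritic cell genes fell, 1 unfolded protein response gene rose and 1 fell, and 1 gene each of the circadian, T and NK cell and plasma cell lists rose. Adipocyte and skeletal muscle genes had 4 and 2 tested members, too few for camera, and none passed.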

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

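Of the alternatives, the pseudocount of 0.1, the fit without intensity trend, sample quality weights, the run term, run 2 alone and quantile normalization were chosen after seeing the data. Tests that need counts, among them voom, were not run. All 132 genes kept their direction under every alternative that tested them. As their groups did not overlap, only the fits that rescaled the libraries could have turned a direction. The total stayed within 1.5 times of 132 with median-ratio scaling (134), scaling to the same total (166), the stricter filter (123), a pseudocount of 0.1 (130) and no trend (135). It was 87 (50 higher, 37 lower) without haemoglobin, immunoglobulin and mitochondrial genes, where 12080 genes were tested, 36 (18 and 18) with no filter, where 27669 were, 49 (33 and 16) at 2-fold or more and 368 (177 and 191) at an adjusted p under 0.1. It was 959 (429 and 530) with the replicate block, 1645 (746 and 899) with the run term, 2173 (1085 and 1088) in run 2 alone, 1970 (955 and 1015) with sample quality weights and 199 (91 lower) with quantile normalization; scaling to the same total gave 101 lower genes. Leaving out 1 library gave 17 to 262 genes, 9 to 160 higher and 7 to 102 lower: 262 without control replicate 1, 33 without control replicate 2, 17 without control replicate 3, 72 without CUMS replicate 1, 19 without CUMS replicate 2 and 17 without CUMS replicate 3. Leaving out 1 library also divided the header code unevenly between the groups, so an effect of this code did not cancel in those fits. Beyond that and the fewer or more genes and libraries, the cause was not tested.

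The azurophil list (camera adjusted p = 0.0606) passed with scaling to the same total (0.0250), without haemoglobin, immunoglobulin and mitochondrial genes (0.0162), with no filter (0.0398), the replicate block (0.0245), the run term (0.0207), run 2 alone (0.0158) and quantile normalization (0.0185), and ranged from 0.00217 without control replicate 1 to 0.607 with 1 library left out (0.00897 without CUMS replicate 2, 0.0335 without CUMS replicate 3). The specific granule list turned to higher without control replicate 1 (0.316), without CUMS replicate 3 (0.955) and with quantile normalization (0.143), and ranged from 0.233 to 0.955. The mature neutrophil list passed with scaling to the same total (0.0409) and ranged from 0.114 to 0.590. Among the other lists that did not pass, the dendritic list (0.104) passed with scaling to the same total (0.0402), the run term (0.0482), and quantile normalization (0.0367). Fry, which tests a list against no change and not against other genes, gave 0.00558 for the dendritic list and 0.0179 for stem and progenitor genes. Myeloid regulators (0.0692) passed with scaling to the same total (0.0402), without haemoglobin, immunoglobulin and mitochondrial genes (0.0367), with no filter (0.0398), the replicate block (0.0308), the run term (0.0253) and run 2 alone (9.32e-04). T and NK cell genes (0.0591) passed with no filter (0.0159) and the stricter filter (0.0461), and circadian clock genes (0.0692) with the run term (0.0482). Unfolded protein response genes (0.239) passed in run 2 alone (0.0146), and ribosomal protein genes (0.239) in run 2 alone (1.21e-04), without haemoglobin, immunoglobulin and mitochondrial genes (0.0367) and with quantile normalization (0.0109). The monocyte list was lost only with the estimated correlation (0.0633) and ranged from 5.23e-06 to 1.45e-04. The cause was not tested.

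Other results that turned, none of them called after turning, had these adjusted p. Plasma cell genes had 0.989 without control replicate 1 (0.0570 to 0.989 with 1 library left out), and megakaryocyte genes 0.610 without control replicate 2 and 0.955 without CUMS replicate 3 (0.501 to 0.955). Endothelial genes had 0.357 with no filter, 0.946, 0.917 and 0.947 without control replicate 1, control replicate 2 and CUMS replicate 1 (0.763 to 0.978), 0.920 in run 2, 0.969 with quantiles and 0.906 by fry. Osteoclast genes had 0.812 without control replicate 1, 0.937 without CUMS replicate 3 (0.520 to 0.937) and 0.799 in run 2, and glycolysis genes 0.850 at the same total and 0.864, 0.936 and 0.712 without control replicate 2, control replicate 3 and CUMS replicate 1 (0.366 to 0.936). Oxidative phosphorylation genes had 0.355 without control replicate 2 and 0.946 without CUMS replicate 1 (0.0102 without control replicate 1, to 0.946), and ribosomal protein genes 0.631 and 0.973 without the same libraries (1.79e-05 without control replicate 1, to 0.973). Hbb-bs had a log2 change of 0 with quantiles, which is no turn of direction, as that method gives genes of the same rank in every library the same value. As log2 changes, Nr3c1 was −0.008 at the same total and −0.068, −0.033 and −0.034 without control replicate 1, CUMS replicate 2 and CUMS replicate 3 (−0.068 to 0.158), Ly6c2 −0.014 and −0.025 without control replicates 2 and 3 (−0.025 to 0.188), S100a8 0.091 without control replicate 1 (−0.175 to 0.091), 0.059 with quality weights and 0.1 in run 2, and Flt3l 0.048 without CUMS replicate 3 (−0.167 to 0.048). The cause was not tested.

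Little can be said of genes below the filter, which the main fit did not test, such as Avpr1a, Avpr1b and Il6 (0.259 to 0.518 FPKM in controls, 0.796 to 1.17 in CUMS).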

Other observations

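The family tests and the tests of explanations in this part were chosen after the values were seen, and so were the genes named and the run term. The limma fit on group alone and the replicate block were chosen before. The families were picked from these same data, and Fisher's exact test takes their members as independent, so its p-values only describe them. Immunoglobulin variable segments were over-represented among the higher genes: 11 of 175 tested were called higher and 1 lower (Fisher's exact test, one-sided, adjusted p = 3.62e-08 over 32 tests; 51 higher and 9 lower with the run term). Among constant genes Ighg1, from 10.8 ± 0.908 to 25.5 ± 5.48 FPKM, and Ighg2c, from 12.4 ± 3.79 to 30.5 ± 5.15, rose (log2 changes 1.14 and 1.26, limma adjusted p = 0.0196 and 0.0343), while Igha and Ighm had log2 changes of 0.13 and −0.20 (adjusted p = 0.825 and 0.481). Small nucleolar RNA genes were higher in 138 of 158 tested, with a median log2 change of 0.43 (0.36 in run 1, 0.49 in run 2), and 11 rose (Fisher's exact test, one-sided, adjusted p = 1.41e-08). Reads of longer transcripts may count for such genes, which was not tested. Snord22, for example, overlaps exons of Snhg1 on the same strand over 126 bp. Histone genes of the replication-dependent clusters were higher in 56 of 59, and 3 rose (Fisher's exact test, one-sided, adjusted p = 0.0131).

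Rbm3, an RNA-binding protein induced by mild cooling, rose from 121 ± 20.8 to 235 ± 7.52 FPKM, with a pseudogene copy, Rbm3-ps, that shares its sequence (log2 changes 0.97 and 0.77, limma adjusted p = 0.0185 and 0.0309). Cirbp, the related cold-inducible gene, was at 27.7 ± 1.96 and 35.6 ± 0.706 FPKM (adjusted p = 0.122, with the replicate block 0.0336). Osm, a cytokine of myeloid cells, rose from 32.3 ± 1.83 to 54.9 ± 0.396 FPKM and Agtr1a, an angiotensin receptor, from 4.32 ± 0.397 to 7.68 ± 0.755 (adjusted p = 0.0115 and 0.0338). Ifitm3, an interferon-inducible membrane protein, fell from 406 ± 45.8 to 224 ± 9.49 FPKM, and the mitochondrial ribosomal RNA mt-Rnr2 from 659 ± 47.7 to 386 ± 38.6 (adjusted p = 0.0179 and 0.0283). Plpp6 was listed at 0 in all 3 control libraries and at 2.87 to 3.02 FPKM in CUMS, while 4430402I18Rik, whose exons overlap those of Plpp6 over 202 bp on the opposite strand, was at 1.48 to 2.02 FPKM in controls and at most 0.0708 in CUMS. Of the 26 tested major histocompatibility genes none was called (0 higher, 0 lower by limma), 2 had values towards higher, and with the run term 12 fell (Fisher's exact test, one-sided, adjusted p = 2.61e-07).

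The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 132 genes, the 9 others at most 0, and 1 split, the real one, gave as many. Among the 4 splits that part all 3 replicate pairs the highest other was also 0, and it was 0 with the replicate block (959 for the real split) and with the run term (1645).

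The lower interferon-stimulated genes could come from the sequencing run (as the header code was read), from a smaller share of monocytes, which express many of them, or from the scaling of the libraries. All 19 tested members were lower in both runs, which argues against the run. Both groups were also divided alike between the runs, so an effect of the run shared by them cancels from the comparison. The mean of the list minus the mean of the monocyte list differed between the groups by −0.50 on the log2 scale (pooled SD 0.076). A loss of monocytes that lowers both lists alike would not give this gap, but that premise was not tested. Members of the monocyte list moved unevenly (Cx3cr1 −1.10, Ly6c2 0.05), so the gap cannot decide whether fewer monocytes of some kind account for it. The median nearest to 0 under the other scalings was −0.69, which argues against scaling. A weaker interferon response in CUMS marrow, or a smaller share of some monocytes or of another cell type that expresses these genes, stays open and was not tested. So does a difference in genetic background or RNA source between the groups, which was not tested for these genes.

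The large and uniform differences of Erdr1, Y-linked genes and immunoglobulin variable segments could come from female cells in the controls, from reads moving between the Erdr1 copies, or from 1 shared RNA source per group, since the labels do not say that replicates were separate animals. Xist reached 0.0312 FPKM at most in a control library, which argues against female cells. The copies of Erdr1 summed to 86.3 ± 12.7 FPKM in controls and 4.91 ± 1.14 in CUMS, 17.6-fold lower, which argues against a move of reads between them. Between same-group libraries of run 2 the variable segments, whose use should differ between animals, differed by 0.220 (median absolute log2), 1.24 times as much as other genes of the same level and exon length (2.05 times against genes of the same level alone), so a shared source cannot be told apart from separate animals with these libraries. The labels name the group under genotype as well as under treatment, which was read as a slip of the form. A difference in genetic background between the groups was not tested and stays open, for these genes and for the other differences between the groups.

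The higher immediate-early genes and single chemokines could come from the run, from another hour of collection, or from heat or handling of the tissue, which induce the same genes. The immediate-early list was joined to the chemokines of the other fixed lists after the values were seen, which gave 22 tested genes. Of these 19 were higher in both runs, and the lower of the median log2 changes of the runs was 0.458 (run 2, against 0.653 in run 1), which argues against the run. An effect of the run shared by the groups would also cancel, since both were divided alike between the runs. The clock genes that peak with Dbp, minus those that peak with Arntl, differed by 0.371 between the groups (pooled SD 0.088, 5 and 3 genes), a shift that either the stress or the hour could give, so these cannot be told apart without the hours of collection. Per1, in neither arm, had a log2 change of 1.25 (limma adjusted p = 0.0997, with the replicate block 0.00210). The heat shock genes Hsph1 and Dnajb1 differed by 0.131 on average (−0.037 and 0.299). The heat-induced Hspa1a and Hspa1b, near the floor at 0.295 to 1.09 FPKM, were lower in every CUMS library than in every control library (differences of −0.421 and −0.349). Genes so near the floor exclude nothing, so heat stays open. Stress itself stays open, since the groups differ in it by design.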
